A study of Canis lupus familiaris with 30 samples.

How the data were processed

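RNA from the left ventricular free wall and the gastrocnemius of 15 golden retrievers was hybridised to Affymetrix Canine Gene 1.0 arrays, 1 array per tissue and dog, 30 in all. Affected dogs carry golden retriever muscular dystrophy (GRMD), an X-linked loss of dystrophin that serves as a large animal model of Duchenne muscular dystrophy. The dogs form 5 groups of 3: normal and GRMD dogs of 6 to 7.5 months (young), normal and GRMD dogs of 12 to 13.5 months (middle), and GRMD dogs of 47, 52 and 93 months (old), for which there was no normal group of that age. A protocol label gives these ages in years, and the age tags of the samples, in months, were used. Gastrocnemius samples come from the medial head, except old GRMD replicate 3, whose label names the lateral head.

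The deposited values are log2 RMA values, which the authors made in Partek Genomics Suite 6.6 by background correction, quantile normalisation and probe summary, followed by an analysis of variance there. The library files and the probe set level are not given in the sources used here. Array medians lay between 4.96 and 5.14, with values from 0.964 to 14.2, and arrays of the same tissue correlated at 0.938 to 0.986 across probe sets. These values were used as given, with no further normalisation in the tests reported first.

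The value table holds 32391 probe sets. The annotation table of the array pairs 16545 of them with 1 gene symbol and 370 with several, and 15476 are not listed in it. Symbols were looked up by gene ID in the RefSeq gene table of the German Shepherd assembly, where 15820 were found and 0 changed. For a gene with more than 1 probe set (516 genes) the probe set with the highest mean over the 30 arrays was taken, which left 15947 genes. No genome coordinates are used.

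Each tissue was fitted with limma 3.58.1 in R 4.3.3, with 5 group means over its 15 arrays and moderated variances (10 residual degrees of freedom before moderation). The contrasts were GRMD against normal averaged over the young and middle classes, GRMD against normal within each class, the middle effect minus the young effect, old GRMD against the mean of the younger GRMD groups, and old GRMD against the mean of both normal groups, where disease and age are mixed. The difference of the averaged GRMD effect between tissues was fitted over 30 arrays and 10 group means with the dog as a random block (correlation 0.0394). Dogs were matched between tissues by group and replicate number, except in middle GRMD. There the number and the age tag disagree, and the age tag put left ventricle replicates 1, 2 and 3 with muscle replicates 1, 3 and 2. A gene passed at an adjusted p under 0.05 (Benjamini-Hochberg over the 15947 genes of a contrast, two-sided). Values written after a gene as "a ± b" are the log2 fold change and its standard error from limma.

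Gene lists (23) and cell type marker lists (16) were fixed before the data were examined, and 38 with at least 5 measured members were tested. The sex-linked list had 0 measured members and was not tested. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 38 lists of a contrast. Beside it stand camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance. For the tissue difference, camera ran on the blocked statistics, and the estimated correlation came from a fit without the block. Counts of list members that passed are given over all genes and adjusted over the list alone.

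The genes named were set by a rule fixed before the data were examined. In the averaged comparisons these are DMD, SPP1 and TIMP1, then the 10 largest rises and 10 largest falls that passed and in which each GRMD dog lay beyond each normal dog of its age class. From each list, up to 4 members that passed with the largest change follow, or, where none passed, 2 of the smallest p. In the other comparisons these are up to 5 rises and 5 falls by size, with members of lists whose test passed. Where under 5 genes passed, the 3 of smallest p were added. Symbols that are only a locus number were left out, and DMD is given in every comparison.

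The steps were tested on simulated data with the spread of each tissue over 15947 genes, with 100 genes changed 1.5-fold and 100 changed 2-fold. In the averaged comparison 52% and 94% of them were recovered in muscle and 66% and 93% in the ventricle. In the young comparison 18% and 71% were recovered in muscle and 10% and 70% in the ventricle, and between old and younger GRMD 32% and 87%, and 35% and 83%. False calls numbered 2 to 9 in each.

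The alternatives tried were quantile normalisation again within the tissue, leaving out probe sets under the 40th percentile of signal, testing every probe set, the variance of each gene alone, fitting only the compared groups, fitting all 30 arrays with the dog as block, array weights, the replicate number as a block, other treatments of the dog, and leaving out each array in turn. Fits without arrays that stood apart, and a contrast of middle against young GRMD muscle, were added after the data were seen. Measures of genes absent from the annotation table are given only as counts.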

Results

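Transcript levels were measured in the left ventricle and the gastrocnemius of 15 golden retrievers, 6 normal and 9 with GRMD, on 30 arrays. Each of the 10 groups (tissue by disease by age class) holds 3 dogs. Levels are log2 RMA values, with array medians from 4.96 to 5.14. Signal was not tested against background, so where a group lies near or under the 25th percentile of the arrays (3.31 to 3.54), as SPP1 (3.48 ± 0.21), MMP12 (3.53 ± 0.30) and GPR34 (3.49 ± 0.11, SD, n = 3) do in young normal muscle, differences from it are bounds. Depth in reads does not apply to arrays, and the 3 arrays of a group limit the precision. The design asks how loss of dystrophin changes limb muscle, which weakens early, and heart, which is affected later, and how both change with age. The bar chart of gene counts shows the 13 comparisons side by side.

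**Figure D1:**
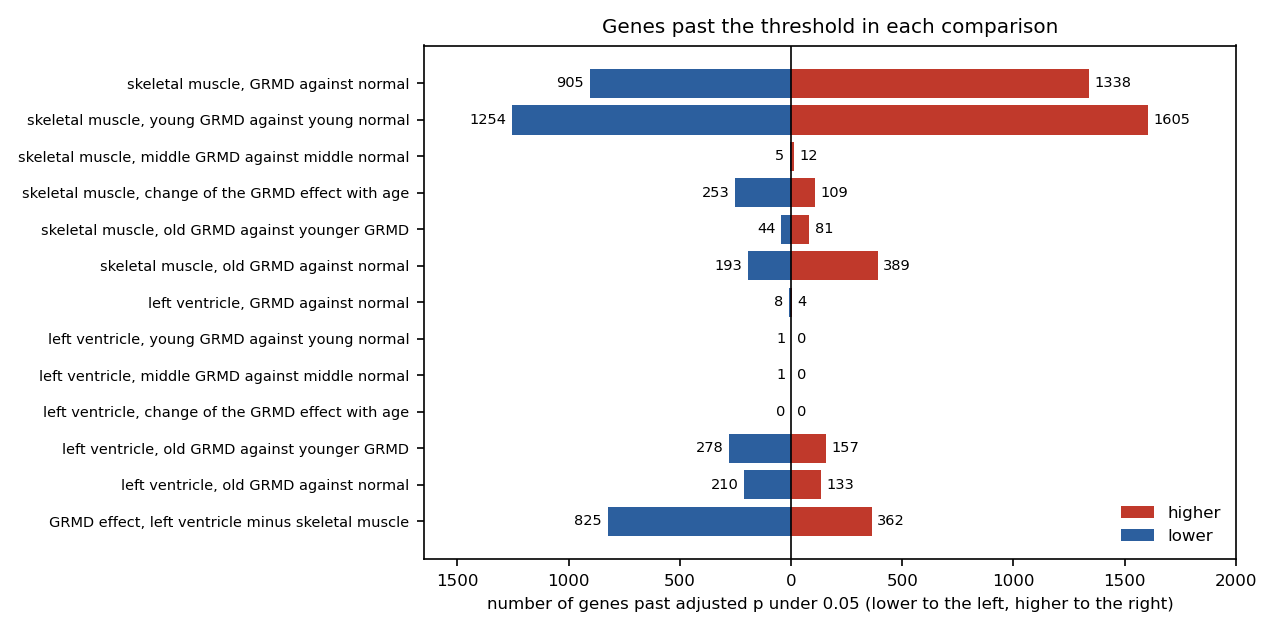
Genes with an adjusted p under 0.05 (limma, 15947 genes) in each of 13 comparisons, as the number of genes, higher to the right and lower to the left. Young GRMD muscle has the longest bars (1605 higher and 1254 lower), the ventricle of young and of middle dogs 1 gene each.

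In skeletal muscle, DMD, the dystrophin gene itself, was lower in GRMD dogs of both age classes together, by 1.30 ± 0.13 (6 GRMD against 6 normal dogs, adjusted p = 9.6e-05). Its level was 9.04 ± 0.19 (SD, n = 3) in young normal and 7.29 ± 0.28 in young GRMD muscle, and 8.74 ± 0.23 and 7.89 ± 0.11 at the middle age. SPP1, which encodes osteopontin, was higher by at least 3.73 ± 0.75 as the mean of the 2 age classes (adjusted p = 0.00408). TIMP1, an inhibitor of matrix proteases, rose by 1.73 ± 0.35 (adjusted p = 0.00448). Neither passed at the middle age, with SPP1 at 8.31 ± 2.82 in normal and 7.13 ± 1.81 in GRMD muscle.

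**Figure D2:**
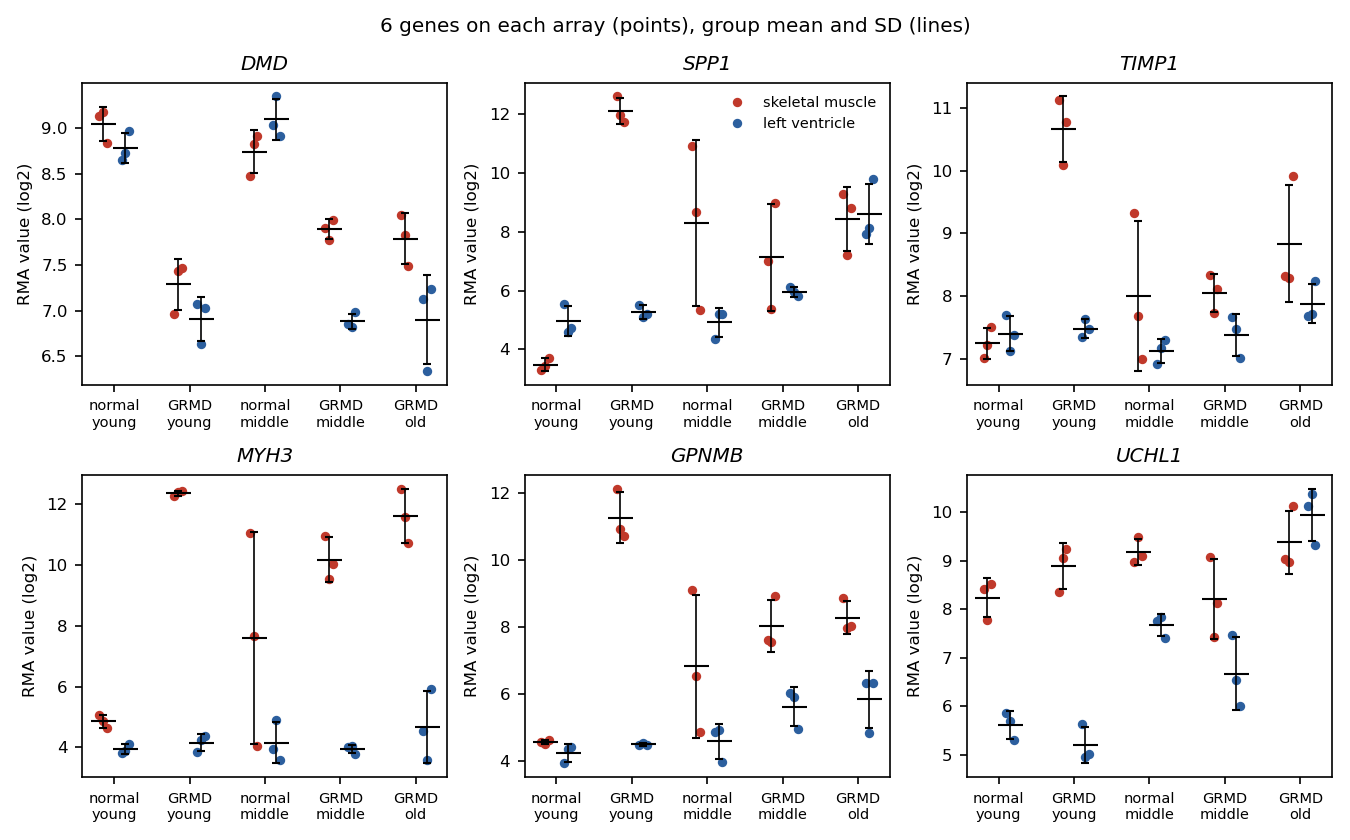
Log2 RMA values of DMD, SPP1, TIMP1, MYH3, GPNMB and UCHL1 on each of the 30 arrays (points) in 5 groups, skeletal muscle in red and left ventricle in blue, with the mean and SD of the 3 dogs as lines. Each GRMD array lies below each normal array for DMD in its tissue, and 2 of the 3 normal middle muscle arrays lie far above the young normal ones for SPP1 and MYH3 (11.05 and 7.67 for MYH3).

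Among genes that passed, had a name other than a LOC number and had every GRMD dog beyond every normal dog of its age class, the largest rises in GRMD muscle were those of MYH8, the perinatal myosin heavy chain (4.41 ± 0.57), and PVALB, the calcium buffer of fast fibres (3.09 ± 0.35). They were followed by TAL2 (2.41 ± 0.50), PAK1 (2.36 ± 0.25), CST6 (2.35 ± 0.32) and EFEMP1 (2.23 ± 0.30). MRC1, the macrophage mannose receptor (2.04 ± 0.29), C1S, a complement protease (2.03 ± 0.32), AHNAK2 (2.01 ± 0.17) and GPR34 (1.89 ± 0.24) came next. The largest falls under the same conditions were those of PFKFB1, a regulator of glycolysis (-2.47 ± 0.36), ADAMTS8, a metalloprotease (-2.40 ± 0.30), B4GALT6 (-2.24 ± 0.23) and FBXO40, a muscle ubiquitin ligase subunit (-1.93 ± 0.19). SLC38A3, a glutamine transporter (-1.89 ± 0.18), FAM184A (-1.79 ± 0.27) and FEZ1 (-1.74 ± 0.42) followed. The last of 10 were SMCO1 (-1.59 ± 0.28), ASPA (-1.55 ± 0.28) and LGI1 (-1.53 ± 0.22). Genes without such a separation include some with larger rises, such as MYH3 (5.04 ± 0.77) and GPNMB (3.95 ± 0.52). In total 2243 of 15947 genes passed, 1338 higher and 905 lower, and 387 and 62 of these changed at least 2-fold. Of 115 named genes that passed, 102 kept their call with each array left out in turn. The other 13 (ACTN3, ANKRD1, SDHB, COX7A1, NDUFA6, HADH, PFKFB3, IFI6, TOP2A, HSPA5, TNNT2, CDH5 and RGS5) lost it without 1 array or more, 12 of them without normal middle replicate 3. Without normal middle replicates 1 and 2, whose SPP1 stood at 10.93 and 8.66, 1303 genes passed, and without these and normal young replicate 2 1044 passed (fits added after the data were seen).

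In the regenerating fibre list of GRMD muscle, 15 of the 20 measured genes rose, 0 fell and 5 did not pass, and 17 rose and 0 fell when adjusted over the list alone. The list passed (camera adjusted p = 1.3e-13, adjusted p = 0.130 with an estimated correlation), with MYH3, the embryonic myosin heavy chain (5.04 ± 0.77), and MYH8. MYL4 (3.30 ± 0.50) and ACTC1 (3.27 ± 0.76), embryonic forms that adult heart also expresses, rose too. Normal middle muscle replicate 1 carried these transcripts too, with a list mean of 7.65 against 5.50 in replicate 3. Among genes of the neuromuscular junction and denervation, 7 of the 14 measured genes rose, 0 fell and 7 did not pass, and 7 rose and 1 fell when adjusted over the list alone. The list passed (camera adjusted p = 0.000109, adjusted p = 0.138 with an estimated correlation), led by the acetylcholine receptor subunits CHRNA1 (2.61 ± 0.43) and CHRNG (2.04 ± 0.40), with RUNX1 (1.66 ± 0.27) and ACHE (1.58 ± 0.23). Of satellite cell genes, 4 of the 10 measured genes rose, 0 fell and 6 did not pass, and 4 rose and 1 fell when adjusted over the list alone. The list passed (camera adjusted p = 0.00408, adjusted p = 0.130 with an estimated correlation), with MYF5, a myogenic transcription factor (1.61 ± 0.25), and MET (1.31 ± 0.22), VCAM1 (0.79 ± 0.19) and CHODL (0.77 ± 0.16). CHRNA1, CHRNG, RUNX1 and MYF5 are regenerating fibre list members too, so these lists overlap. Of cell cycle genes, 11 of the 28 measured genes rose, 0 fell and 17 did not pass, and 16 rose and 0 fell when adjusted over the list alone. The list passed (camera adjusted p = 6.2e-09, adjusted p = 0.333 with an estimated correlation), with CDK1 (1.45 ± 0.35), RRM2 (1.35 ± 0.30), TOP2A (1.17 ± 0.33) and MCM6 (0.97 ± 0.24).

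In GRMD muscle, for macrophage markers, 19 of the 23 measured genes rose, 0 fell and 4 did not pass, and 21 rose and 0 fell when adjusted over the list alone. Macrophage genes passed as a list (camera adjusted p = 9.4e-19, adjusted p = 0.138 with an estimated correlation), with GPNMB (3.95 ± 0.52), the oxidase subunit CYBB (2.66 ± 0.47), AIF1 (2.52 ± 0.45) and TYROBP (2.44 ± 0.42). For complement, 11 of the 15 measured genes rose, 0 fell and 4 did not pass, and 11 rose and 0 fell when adjusted over the list alone. Complement genes passed as a list (camera adjusted p = 3.8e-11, adjusted p = 0.130 with an estimated correlation), with VSIG4 (2.28 ± 0.33), CLU (2.05 ± 0.38), C1S (2.03 ± 0.32) and C1R (1.80 ± 0.27). For chemokines and cytokines, 14 of the 29 measured genes rose, 0 fell and 15 did not pass, and 16 rose and 0 fell when adjusted over the list alone. The list passed (camera adjusted p = 6.1e-08, adjusted p = 0.138 with an estimated correlation), with CCL2, which attracts monocytes (2.84 ± 0.63), IL18 (2.26 ± 0.41) and CXCL16 (1.77 ± 0.28). For antigen presentation, 10 of the 18 measured genes rose, 1 fell and 7 did not pass, and 10 rose and 1 fell when adjusted over the list alone. Antigen presentation genes passed as a list (camera adjusted p = 6.8e-07, adjusted p = 0.138 with an estimated correlation), with the class II genes DLA-DRA (2.49 ± 0.37) and DLA-DQA1 (2.36 ± 0.33), and CTSS (2.77 ± 0.38) and CD74 (1.79 ± 0.26). For interferon response, 5 of the 22 measured genes rose, 0 fell and 17 did not pass, and 6 rose and 0 fell when adjusted over the list alone. Interferon response genes passed as a list (camera adjusted p = 0.00233, adjusted p = 0.333 with an estimated correlation), with IFI6 (0.94 ± 0.27), OAS2 (0.89 ± 0.19), IFI44L (0.82 ± 0.20) and IFIH1 (0.59 ± 0.14). Markers of T and NK cells (1 of 19 rose, CD2 (1.90 ± 0.38), camera adjusted p = 0.441) and B and plasma cells (0 of 11 passed, 0.998) did not pass as lists. Neither did mast cells (1 of 9 rose, CPA3 (0.90 ± 0.17), 0.285), neutrophils (0 of 11, 0.648) or erythroid cells (0 of 6, 0.648). Among these the smallest p were those of POU2AF1 (0.37 ± 0.18, adjusted p = 0.197), IL1R2 (0.64 ± 0.33, adjusted p = 0.216) and SLC4A1 (-0.22 ± 0.12, adjusted p = 0.248).

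In the extracellular matrix list, 17 of the 30 measured genes rose, 0 fell and 13 did not pass, and 20 rose and 0 fell when adjusted over the list alone. The list passed (camera adjusted p = 4.9e-13, adjusted p = 0.130 with an estimated correlation), with the matricellular POSTN (1.86 ± 0.32), fibronectin FN1 (1.83 ± 0.28), collagen COL1A1 (1.71 ± 0.29) and THBS1 (1.65 ± 0.34). These are again means over both age classes. POSTN lay at 8.49 to 9.52 in young and 4.83 to 5.96 in middle GRMD muscle, against 4.83 to 5.23 and 4.69 to 6.41 in normal muscle. Of matrix proteases and inhibitors, 11 of the 18 measured genes rose, 1 fell and 6 did not pass, and 12 rose and 1 fell when adjusted over the list alone. The list passed (camera adjusted p = 4.3e-08, adjusted p = 0.130 with an estimated correlation), with CTSS (2.77 ± 0.38), CTSK (2.55 ± 0.39), MMP12 (2.55 ± 0.53) and TIMP1 (1.73 ± 0.35). Of TGF-beta pathway genes, 8 of the 18 measured genes rose, 0 fell and 10 did not pass, and 8 rose and 0 fell when adjusted over the list alone. TGF-beta pathway genes passed as a list (camera adjusted p = 0.000179, adjusted p = 0.130 with an estimated correlation), with FST, an activin antagonist (1.58 ± 0.27), TGFBI (1.43 ± 0.25) and LTBP1 (1.09 ± 0.15). Of fibroblast and fibroadipogenic progenitor markers, 8 of the 15 measured genes rose, 0 fell and 7 did not pass, and 10 rose and 1 fell when adjusted over the list alone. The list passed (camera adjusted p = 1.2e-05, adjusted p = 0.184 with an estimated correlation), with S100A4 (2.62 ± 0.41), THY1 (1.16 ± 0.27), DPT (1.11 ± 0.22) and FAP (1.08 ± 0.26). In the dystrophin-associated complex, 6 of the 18 measured genes rose, 2 fell and 10 did not pass, and 7 rose and 2 fell when adjusted over the list alone. The list passed (camera adjusted p = 0.0194, adjusted p = 0.456 with an estimated correlation), with NOS1, the synthase that dystrophin anchors (-1.17 ± 0.14), lower along with DMD, and LAMA2 (1.07 ± 0.18) and SNTB1 (0.78 ± 0.19) higher.

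In GRMD muscle, of oxidative phosphorylation genes, 0 of the 41 measured genes rose, 4 fell and 37 did not pass, and 0 rose and 7 fell when adjusted over the list alone. Oxidative phosphorylation genes passed as a list (camera adjusted p = 1.3e-07, adjusted p = 0.523 with an estimated correlation), with COX10 (-0.50 ± 0.12), SDHB (-0.35 ± 0.11), COX7A1 (-0.32 ± 0.10) and NDUFA6 (-0.29 ± 0.093). Of fatty acid oxidation genes, 1 of the 25 measured genes rose, 6 fell and 18 did not pass, and 1 rose and 10 fell when adjusted over the list alone. Fatty acid oxidation genes passed as a list (camera adjusted p = 0.000378, adjusted p = 0.456 with an estimated correlation), with the isomerase ECI1 (-0.85 ± 0.13), the regulator PPARA (-0.83 ± 0.19), CPT2 (-0.70 ± 0.15) and HADH (-0.62 ± 0.17). Of glycolysis and glycogen genes, 1 of the 20 measured genes rose, 3 fell and 16 did not pass, and 1 rose and 6 fell when adjusted over the list alone. Glycolysis and glycogen genes passed as a list (camera adjusted p = 0.0218, adjusted p = 0.553 with an estimated correlation), with PFKFB1 and PHKA1 (-0.86 ± 0.15) and PHKG1 (-0.60 ± 0.15) lower and PFKFB3 (0.81 ± 0.24) higher. Of endothelial markers, 0 of the 16 measured genes rose, 3 fell and 13 did not pass, and 0 rose and 6 fell when adjusted over the list alone. Endothelium genes passed as a list (camera adjusted p = 0.000617, adjusted p = 0.403 with an estimated correlation), and these 3 were the vascular growth factor receptors FLT1 (-0.95 ± 0.16) and KDR (-0.87 ± 0.19) and the junction protein CDH5 (-0.86 ± 0.25).

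Stress and translation lists shifted as well. For immediate early and heat shock genes, 5 of the 22 measured genes rose, 0 fell and 17 did not pass, and 5 rose and 0 fell when adjusted over the list alone. Immediate early and heat shock genes passed as a list (camera adjusted p = 0.0207, adjusted p = 0.566 with an estimated correlation), with EGR2 (1.73 ± 0.41), ZFP36 (1.56 ± 0.36), MYC (1.37 ± 0.30) and JUNB (1.34 ± 0.27). For endoplasmic reticulum stress, 5 of the 17 measured genes rose, 2 fell and 10 did not pass, and 8 rose and 2 fell when adjusted over the list alone. Endoplasmic reticulum stress genes passed as a list (camera adjusted p = 0.0370, adjusted p = 0.566 with an estimated correlation), with ASNS (0.85 ± 0.19), HSPA5 (0.81 ± 0.24), PDIA3 (0.75 ± 0.16) and DDIT3 (-0.74 ± 0.17). For cytosolic ribosomal proteins, 2 of the 33 measured genes rose, 0 fell and 31 did not pass, and 2 rose and 0 fell when adjusted over the list alone. Cytosolic ribosomal proteins passed as a list (camera adjusted p = 0.00160, adjusted p = 0.235 with an estimated correlation), the 2 being RPL3 (1.32 ± 0.22) and RPSA (0.73 ± 0.092). In all, 21 of 38 lists passed with the preset correlation (17 up, 4 down), 0 with an estimated correlation and 19 by fry.

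The remaining lists did not pass in muscle. Fast fibre genes had 4 of 15 members higher (PVALB (3.09 ± 0.35), MYH1 (2.87 ± 0.50), MYH4 (1.19 ± 0.20) and ACTN3 (0.99 ± 0.30), camera adjusted p = 0.111). Slow fibre genes had 0 of 10 past the threshold (0.118), with MYBPC1 (-0.24 ± 0.11, adjusted p = 0.142) and MYH7B (-0.43 ± 0.22, adjusted p = 0.223) closest. Oxidative stress genes had 4 higher and 2 lower of 20 (0.235), with MT2A (2.95 ± 0.50), CYBB (2.66 ± 0.47) and CYBA (1.23 ± 0.25) higher and NOX4 (adjusted p = 0.0153) lower. Atrophy and proteolysis genes had FBXO40 (-1.93 ± 0.19) lower and FBXO30 (0.52 ± 0.12) higher of 13 (0.146), and calcium handling FKBP1A (0.53 ± 0.12) of 23 (0.296). Adipocyte markers had THRSP (-0.88 ± 0.20) lower and SCD (0.77 ± 0.19) higher of 14 (0.936). Median, mean and test differed in sign for cardiac stress and remodelling (median -0.19, mean 0.021, test down, adjusted p = 0.370), where LGALS3 (2.62 ± 0.36) and ANKRD1 (1.22 ± 0.32) were higher and NPR3 (-1.45 ± 0.28) and CORIN (-0.54 ± 0.12) lower. The same held for skeletal muscle fibre (median -0.032, mean 0.21, test up, adjusted p = 0.694, 2 of 14 higher, MYH1 and ACTN3) and for cardiomyocyte markers (median -0.28, mean 0.39, test down, 0.694, 3 of 13 higher). Those 3, MYL4, ACTC1 and TNNT2 (2.57 ± 0.77), are also in the regenerating fibre list, and MYL4 was the member that rose among 7 atrial markers (median -0.016, mean 0.34, test up, 0.998). It held again for smooth muscle and pericyte markers (median 0.051, mean -0.039, test down, 0.841), where RGS5 (-0.75 ± 0.24) and ABCC9 (-0.54 ± 0.13) were lower of 13, and for Schwann cell and nerve (median -0.18, mean 0.050, test down, 0.449), where EGR2 was higher of 9. Normal young muscle replicate 2 carried heart transcripts, with TNNT2 at 10.5 and RYR2 at 7.39, against 5.30 and 3.61 in replicate 1.

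In young muscle DMD was lower by 1.75 ± 0.18 (3 against 3 dogs, adjusted p = 7.5e-05). MYH3 (7.49 ± 1.09), GPNMB (6.71 ± 0.73), MYH8 (5.94 ± 0.81) and MYL4 (5.46 ± 0.71) rose, with TIMP1 at 3.40 ± 0.50. SPP1 rose by at least 8.63 ± 1.05. The largest falls were those of PFKFB1 (-3.63 ± 0.50), FBXO40 (-3.29 ± 0.27), MSS51, a mitochondrial protein of muscle (-3.08 ± 0.47), ADAMTS8 (-2.85 ± 0.43) and B4GALT6 (-2.59 ± 0.33). In the macrophage list 20 of the 23 measured genes rose, 0 fell and 3 did not pass, and 22 rose and 0 fell when adjusted over the list alone. Macrophage genes passed as a list (camera adjusted p = 4.5e-23, adjusted p = 0.107 with an estimated correlation). In the regenerating fibre list 15 of the 20 measured genes rose, 0 fell and 5 did not pass, and 16 rose and 0 fell when adjusted over the list alone. Regenerating fibre genes passed as a list (camera adjusted p = 4.1e-13, adjusted p = 0.107 with an estimated correlation). Of cell cycle genes 20 of the 28 measured genes rose, 0 fell and 8 did not pass, and 22 rose and 0 fell when adjusted over the list alone. Cell cycle genes passed as a list (camera adjusted p = 1.1e-12, adjusted p = 0.221 with an estimated correlation), with RRM2 (2.50 ± 0.42), CDK1 (2.47 ± 0.49), TOP2A (2.18 ± 0.46) and KIF11 (1.92 ± 0.48). Chemokine genes included CCL2 (5.40 ± 0.89), IL18 (4.26 ± 0.58) and CCL3 (3.58 ± 0.58) (camera adjusted p = 2.7e-11, adjusted p = 0.107 with an estimated correlation). Matrix genes included POSTN (3.78 ± 0.46), TNC (3.07 ± 0.43) and THBS1 (2.95 ± 0.47) (camera adjusted p = 4.2e-12, adjusted p = 0.107 with an estimated correlation). Proteases included MMP12 (5.29 ± 0.75), CTSS (4.96 ± 0.54) and CTSK (4.27 ± 0.55) (camera adjusted p = 1.0e-07, adjusted p = 0.107 with an estimated correlation).

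In young GRMD muscle, of fatty acid oxidation genes 0 of the 25 measured genes rose, 11 fell and 14 did not pass, and 1 rose and 14 fell when adjusted over the list alone. Fatty acid oxidation genes passed as a list (camera adjusted p = 1.2e-05, adjusted p = 0.310 with an estimated correlation), with PPARA (-1.42 ± 0.27), ECI1 (-1.14 ± 0.19), CPT2 (-1.05 ± 0.21) and MLYCD (-0.99 ± 0.13). Of glycolysis and glycogen genes 0 of the 20 measured genes rose, 8 fell and 12 did not pass, and 0 rose and 11 fell when adjusted over the list alone. Glycolysis and glycogen genes passed as a list (camera adjusted p = 8.3e-05, adjusted p = 0.250 with an estimated correlation), with FBP2 (-1.38 ± 0.27), PHKA1 (-1.35 ± 0.21) and SLC2A4 (-1.17 ± 0.29) beside PFKFB1. Oxidative phosphorylation (camera adjusted p = 1.0e-06), endothelium (0.00352) and atrophy and proteolysis (0.0200) lay lower, with 8, 5 and 3 members past the threshold. In that order these had adjusted p = 0.486, 0.453 and 0.479 with an estimated correlation. MSTN, the growth inhibitor myostatin, fell by 2.28 ± 0.37 within a TGF-beta list in which 9 of 18 rose (camera adjusted p = 9.4e-05, adjusted p = 0.107 with an estimated correlation). A total of 2859 genes passed, 1605 higher and 1254 lower, and 22 of 38 lists, 0 with an estimated correlation and 21 by fry. Without GRMD young replicate 1, whose macrophage mean was 8.82 against 7.38 and 7.33 in the others, 1608 genes passed, and 17 of 87 named genes lost their call without 1 array or more, 13 of them without that one. Without normal middle arrays 1 and 2 and the normal young array with heart transcripts 1819 passed (added after the data were seen).

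At the middle age, DMD in muscle was -0.85 ± 0.18 against the normal dogs, which missed the threshold (adjusted p = 0.0851, each GRMD array below each normal array). Genes of fast fibres rose: MYH1, a fast myosin heavy chain (4.34 ± 0.71), PVALB (3.46 ± 0.50) and MYH4 (1.59 ± 0.28). The list had 3 of 15 members past the threshold and 4 adjusted over the list alone (camera adjusted p = 0.00118, adjusted p = 0.849 with an estimated correlation). GRB14, an adaptor of insulin receptor signalling (2.37 ± 0.43), FGL1 (1.61 ± 0.28) and the microfibril gene MFAP5 (1.17 ± 0.19) rose too. SLC38A3 (-1.91 ± 0.25), B4GALT6 (-1.89 ± 0.33), BCHE, butyrylcholinesterase (-1.49 ± 0.26), MTIF3 (-1.06 ± 0.18) and HTRA4 (-0.90 ± 0.15) fell. Regenerating fibre genes lay higher as a list (0 of 20 past, 2 adjusted over the list alone, camera adjusted p = 0.000162, adjusted p = 0.706 with an estimated correlation). Extracellular matrix genes did too (0 of 30 past, 10 adjusted over the list alone, camera adjusted p = 1.1e-05, adjusted p = 0.706 with an estimated correlation). Among the members, MYH8 (2.89 ± 0.81, adjusted p = 0.190), COL6A3 (1.07 ± 0.22, adjusted p = 0.0640) and COL14A1 (1.54 ± 0.32, adjusted p = 0.0640) missed the threshold.

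In total 17 genes passed at the middle age, 12 higher and 5 lower, with 1726 at an unadjusted p under 0.05. Of these, 7 of the 12 and 5 of the 5 were also called in young dogs in the same direction, where independent calls would give 1.21 and 0.393. Complement (camera adjusted p = 0.00118), fibroblast (0.000777) and dystrophin complex genes (0.000746) lay higher as lists. These had adjusted p = 0.706, 0.706 and 0.706 with an estimated correlation. Lower were oxidative phosphorylation (camera adjusted p = 0.00164) and endothelium (0.00990). They had adjusted p = 0.900 and 0.849 with an estimated correlation. The other passing lists were those of matrix proteases (camera adjusted p = 0.00640), TGF-beta (0.0428), denervation (0.0188) and skeletal fibre genes (0.0181). In turn they had adjusted p = 0.759, 0.706, 0.706 and 0.849 with an estimated correlation. So 12 of 38 lists passed, 0 with an estimated correlation and 0 by fry. The gene count rests on single arrays: by limma it was 65 without normal middle replicate 1, 0 without replicate 2 and 0 without replicate 3. It was 4, 0 and 0 without GRMD middle replicates 1, 2 and 3. Of 11 named genes 0 kept the call in each of these fits, and 29 genes passed without normal middle replicates 1 and 2 together, which leaves 1 array assumed to vary like the other groups.

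The GRMD effect in muscle differed between the age classes. The DMD deficit was 0.91 ± 0.26 smaller at the middle age, which missed the threshold (adjusted p = 0.0818). Inflammatory genes in excess in young GRMD muscle were not detectably so at the middle age, with GPNMB at -5.50 ± 1.03, CCL2 at -5.13 ± 1.26 and AIF1 at -4.66 ± 0.91 (middle effect minus young effect). SPP1 (-9.81 ± 1.49) and the elastase MMP12 (-5.48 ± 1.06) moved at least that far. Part of these changes is a higher level in the normal middle dogs, of which replicates 1 and 2 carry such transcripts. SPP1 went from 3.48 ± 0.21 to 8.31 ± 2.82 in normal and from 12.11 ± 0.45 to 7.13 ± 1.81 in GRMD dogs (SD, n = 3), and GPNMB from 4.57 ± 0.066 to 6.83 ± 2.14 in normal dogs. TIMP1 changed by -3.35 ± 0.70 (adjusted p = 0.0234). Genes that were lower in young GRMD muscle had no detectable deficit at the middle age, namely MSTN (3.38 ± 0.52), FBXO40 (2.73 ± 0.39), FRMD3 (2.40 ± 0.57), MPP7 (2.27 ± 0.32) and FMO2 (2.19 ± 0.46). For macrophage genes 0 of the 23 measured genes rose, 16 fell and 7 did not pass, and 0 rose and 20 fell when adjusted over the list alone. Macrophage genes passed as a list (camera adjusted p = 6.6e-24, adjusted p = 0.180 with an estimated correlation). Regenerating fibre genes had 7 of 20 lower (camera adjusted p = 3.0e-08, adjusted p = 0.228 with an estimated correlation), with MYL4 (-4.32 ± 1.01), CHRNG (-3.28 ± 0.80), MYMK (-3.20 ± 0.68) and MYF5 (-2.77 ± 0.50), where MYMK drives myoblast fusion. Cell cycle genes had 2 of 28 lower and 20 adjusted over the list alone (camera adjusted p = 3.1e-12, adjusted p = 0.240 with an estimated correlation). Glycolysis genes had 1 of 20 higher and 10 adjusted over the list alone (camera adjusted p = 3.2e-07, adjusted p = 0.224 with an estimated correlation).

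The change with age passed for 362 genes, 109 with a more positive and 253 with a more negative effect at the middle age, and for 24 of 38 lists, 0 with an estimated correlation and 8 by fry. Complement went down (camera adjusted p = 3.9e-08, adjusted p = 0.224 with an estimated correlation), with VSIG4 (-3.71 ± 0.66), C5AR1 (-2.97 ± 0.48) and C3AR1 (-2.55 ± 0.46). Antigen presentation did too (camera adjusted p = 5.5e-07, adjusted p = 0.224 with an estimated correlation), with CTSS (-4.38 ± 0.76) and DLA-DMA (-1.84 ± 0.37). So did matrix genes (camera adjusted p = 3.6e-05, adjusted p = 0.392 with an estimated correlation), with POSTN (-3.85 ± 0.64), TNC (-2.93 ± 0.61) and BGN (-1.70 ± 0.35). Fatty acid oxidation went up (camera adjusted p = 1.3e-05, adjusted p = 0.392 with an estimated correlation), with MLYCD (1.02 ± 0.18). The count was 164 without normal young replicate 1, 87 without normal young replicate 2, and 225 without GRMD young replicate 1. It was 92 and 208 without normal middle replicates 1 and 2, and 175, 158 and 168 without GRMD middle replicates 1, 2 and 3. Leaving out 2 arrays of 1 group gave 0 to 1278 genes. It was 0 without normal middle replicates 1 and 2, and also without normal young replicates 2 and 3 and GRMD middle replicates 2 and 3 or 1 and 2. The median change of the 362 genes, chosen by this call, was 1.59 with all arrays and 1.45 without normal middle replicates 1 and 2. Of named genes, 26 of 42 lost their call without normal young replicate 2.

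Old GRMD muscle was compared with the young and middle GRMD mean. DMD did not differ detectably (0.20 ± 0.16, adjusted p = 0.627). ABCC5 (2.04 ± 0.30), FGL1 (1.98 ± 0.24), KBTBD8 (1.84 ± 0.34), RAI14 (1.64 ± 0.30) and PDE4A (1.60 ± 0.22) rose. PVALB (-2.61 ± 0.43), MYMK (-1.95 ± 0.42), CRABP2 (-1.95 ± 0.35), LIPA (-1.89 ± 0.37) and POSTN (-1.86 ± 0.39) were lower. Atrophy and proteolysis genes were higher, with BNIP3 (0.84 ± 0.18) the 1 of 13 past the threshold and 11 adjusted over the list alone (camera adjusted p = 6.0e-10, adjusted p = 0.346 with an estimated correlation). Extracellular matrix genes were lower, with POSTN and OGN (-1.34 ± 0.29) past the threshold of 30 and 13 adjusted over the list alone (camera adjusted p = 4.9e-10, adjusted p = 0.346 with an estimated correlation). So were macrophage genes, with 0 of 23 and 15 adjusted over the list alone (camera adjusted p = 2.0e-11, adjusted p = 0.430 with an estimated correlation).

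Cell cycle (camera adjusted p = 1.6e-08), antigen presentation (5.6e-07), immediate early (2.0e-06), chemokine (1.0e-05) and regenerating fibre genes (0.000777) were lower as lists in old muscle. Their adjusted p were 0.456, 0.346, 0.456, 0.430 and 0.456 with an estimated correlation. Old against middle was not tested. In total 125 genes passed, 81 higher and 44 lower, and 13 of 38 lists, 0 with an estimated correlation and 2 by fry. Old replicate 3, labelled lateral head, had S100A8 at 9.62 and TIMP1 at 9.91, above the other old arrays. The count was 65, 29 and 8 without GRMD middle replicates 1, 2 and 3, and 0, 398 and 8 without GRMD old replicates 1, 2 and 3, and 13 of 13 named genes lost their call without old replicate 1.

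Against the younger normal dogs, DMD in old GRMD muscle was lower by 1.11 ± 0.16 (3 against 6 dogs, adjusted p = 0.00256). MYH3 (5.38 ± 0.94), MYH8 (4.74 ± 0.70), MT2A (3.33 ± 0.62), MYL4 (2.94 ± 0.62) and PMAIP1 (2.90 ± 0.64) were higher. ADAMTS8 (-2.60 ± 0.37), ECRG4 (-2.57 ± 0.55), EXTL1 (-2.35 ± 0.27), PFKFB1 (-2.19 ± 0.43) and MGST2 (-2.07 ± 0.43) were lower. Regenerating fibre genes had 3 of 20 higher and 11 adjusted over the list alone (camera adjusted p = 2.6e-06, adjusted p = 0.591 with an estimated correlation). Complement genes had 6 of 15 higher (camera adjusted p = 1.0e-05, adjusted p = 0.591 with an estimated correlation), with CLU (2.64 ± 0.46), C1S (1.66 ± 0.39), CFI (1.47 ± 0.19) and C1R (1.23 ± 0.33). Macrophage markers had GPNMB (2.59 ± 0.63) and MRC1 (1.36 ± 0.35) higher of 23 (camera adjusted p = 4.2e-05, adjusted p = 0.718 with an estimated correlation). Atrophy genes had FBXO30 (1.03 ± 0.15) and FOXO3 (0.66 ± 0.15) higher and FBXO40 (-1.39 ± 0.24) lower of 13 (camera adjusted p = 0.000390, adjusted p = 0.591 with an estimated correlation). Oxidative phosphorylation had 0 of 41 past the threshold and 20 lower adjusted over the list alone (camera adjusted p = 5.2e-12, adjusted p = 0.679 with an estimated correlation). Endothelial KDR (-1.10 ± 0.24), ENG (-0.86 ± 0.21) and FLT1 (-0.80 ± 0.20) were lower of 16 (camera adjusted p = 5.3e-05, adjusted p = 0.591 with an estimated correlation).

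In this comparison, where age and disease are mixed, 582 genes passed, 389 higher and 193 lower, and 11 of 38 lists, 0 with an estimated correlation and 0 by fry. Of the protease list MMP2 (1.38 ± 0.29), ADAMTS5 (1.06 ± 0.18) and TIMP2 (1.02 ± 0.23) rose (camera adjusted p = 0.00151, adjusted p = 0.645 with an estimated correlation). Of the TGF-beta list TGFBR2 (0.93 ± 0.20), LTBP1 (0.90 ± 0.19) and TGFBR1 (0.82 ± 0.19) rose (camera adjusted p = 0.0232, adjusted p = 0.591 with an estimated correlation). Of the denervation list the receptor kinase MUSK (1.59 ± 0.31) did (camera adjusted p = 0.0410, adjusted p = 0.679 with an estimated correlation). The fatty acid oxidation list was lower (camera adjusted p = 0.00103, adjusted p = 0.718 with an estimated correlation). The count was 315 and 269 without normal young replicates 1 and 3, 275 and 252 without normal middle replicates 2 and 3, and 104, 1064 and 102 without GRMD old replicates 1, 2 and 3. It was 307 without normal middle replicates 1 and 2, and 28 of 33 named genes lost their call without 1 array or more, 25 of them without old replicate 3.

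In the left ventricle DMD was -2.04 ± 0.15 in GRMD dogs of both age classes (6 against 6, adjusted p = 2.2e-06). It went from 8.78 ± 0.17 to 6.91 ± 0.24 in young and from 9.09 ± 0.23 to 6.89 ± 0.082 in middle dogs (SD, n = 3). SPP1 (0.67 ± 0.27, adjusted p = 0.525) and TIMP1 (0.17 ± 0.14, adjusted p = 0.847) did not pass. PRR32 (2.26 ± 0.35), PFKP, a phosphofructokinase isoform (1.29 ± 0.18), the matricellular CCN3 (0.93 ± 0.15) and NT5C2, a nucleotidase (0.90 ± 0.16), rose. SERPINB6, a protease inhibitor (-0.99 ± 0.14), ALDOC, an aldolase (-0.89 ± 0.14), and CHST15 (-0.84 ± 0.15) fell. ACSL6, an acyl-CoA synthetase (-0.70 ± 0.10), ADIPOR2, an adiponectin receptor (-0.69 ± 0.12), and CMTM8 (-0.63 ± 0.11) fell as well. In each of these, every GRMD dog lay beyond every normal dog of its age class.

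A total of 12 genes passed in the ventricle, 4 higher and 8 lower, with 1256 at an unadjusted p under 0.05. DMD kept its call with each array left out. The count was 7, 7 and 5 without normal young replicates 1, 2 and 3, and 5, 5 and 5 without GRMD young replicates 1, 2 and 3. It was 1 and 6 without normal middle replicates 2 and 3, and 6 and 4 without GRMD middle replicates 2 and 3. The other 10 named genes lost their call without normal middle replicate 2. With the replicate number as a block 5 passed, and without the 3 arrays that stood apart (normal young 1, normal middle 3 and old 3, a fit added after the data were seen) DMD alone did.

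As lists, 10 of 38 shifted in the ventricle with the preset correlation (2 up, 8 down), 0 with an estimated correlation and 0 by fry, and each had 0 members past the threshold over all genes. Lower were glycolysis and glycogen genes (median -0.17, camera adjusted p = 0.000285, adjusted p = 0.348 with an estimated correlation). So were oxidative phosphorylation (camera adjusted p = 0.00187), interferon response (0.00187), endothelium (0.00187) and cell cycle (0.0218). In that order these had adjusted p = 0.629, 0.532, 0.539 and 0.539 with an estimated correlation. The other lower lists were smooth muscle and pericytes (camera adjusted p = 0.0205), mast cells (0.0357) and fast fibre genes (0.0205). Those had adjusted p = 0.621, 0.532 and 0.624 with an estimated correlation. In the interferon list 1 of 22 was lower adjusted over the list alone. Higher were immediate early genes (camera adjusted p = 0.0155, adjusted p = 0.629 with an estimated correlation, 4 of 22 adjusted over the list alone). Cytosolic ribosomal proteins were too (camera adjusted p = 0.0158, adjusted p = 0.539 with an estimated correlation). Named members that missed the threshold over all genes include GPD1 (-1.29 ± 0.24, adjusted p = 0.0549), KCNJ8 (-0.80 ± 0.16, adjusted p = 0.0873), MYOZ1 (-1.16 ± 0.26, adjusted p = 0.131) and IER3 (1.15 ± 0.27, adjusted p = 0.151). Normal middle ventricle replicate 3 carried skeletal fibre transcripts, with a fast fibre list mean of 6.99 against 5.30 and 5.62 in the others of its group.

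Other lists did not pass in the ventricle, given here with the camera adjusted p. Among muscle lists these were slow fibre genes (0.207), neuromuscular junction and denervation (0.570), atrophy and proteolysis (0.0801), skeletal muscle fibre (0.144) and satellite cell (0.236). Of the heart lists they were cardiac stress and remodelling (0.592), cardiomyocyte (0.688), atrial cardiomyocyte (0.470) and fatty acid oxidation (0.780). Of the immune and blood lists they were antigen presentation (0.180), complement (0.207), B and plasma cell (0.698), neutrophil (0.234) and erythroid (0.0958). Of the matrix lists they were extracellular matrix (0.572), matrix proteases and inhibitors (0.632), TGF-beta pathway (0.727) and fibroblast and fibroadipogenic progenitor (0.780). Each had 0 members past the threshold. Median, mean and test differed in sign, none of them passing, for regenerating fibre genes (0.981, median -0.0043, mean 0.0032, test up), dystrophin-associated complex (0.981, median 0.031, mean -0.077, test down) and calcium handling (0.420, median 0.00055, mean -0.057, test down). They also differed for endoplasmic reticulum stress (0.981, median -0.013, mean -0.0022, test up), oxidative stress response (0.981, median -0.0050, mean -0.017, test up) and chemokines and cytokines (0.981, median 0.0025, mean 0.0051, test down). The same was seen for macrophage (0.981, median -0.015, mean 0.026, test up) and T and NK lymphocyte (0.981, median -0.050, mean 0.0057, test down), and for adipocyte (0.981, median 0.025, mean -0.049, test up) and Schwann cell and nerve (0.981, median -0.0017, mean 0.0074, test up). Of these lists the dystrophin-associated complex had 1 member past the threshold, DMD. Named members of other lists that missed it include NOX4 (-1.08 ± 0.27, adjusted p = 0.186), C3 (0.69 ± 0.19, adjusted p = 0.260) and UCP3 (-1.27 ± 0.36, adjusted p = 0.300), and the mast cell gene CPA3 (-0.60 ± 0.16, adjusted p = 0.236).

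**Figure D3:**
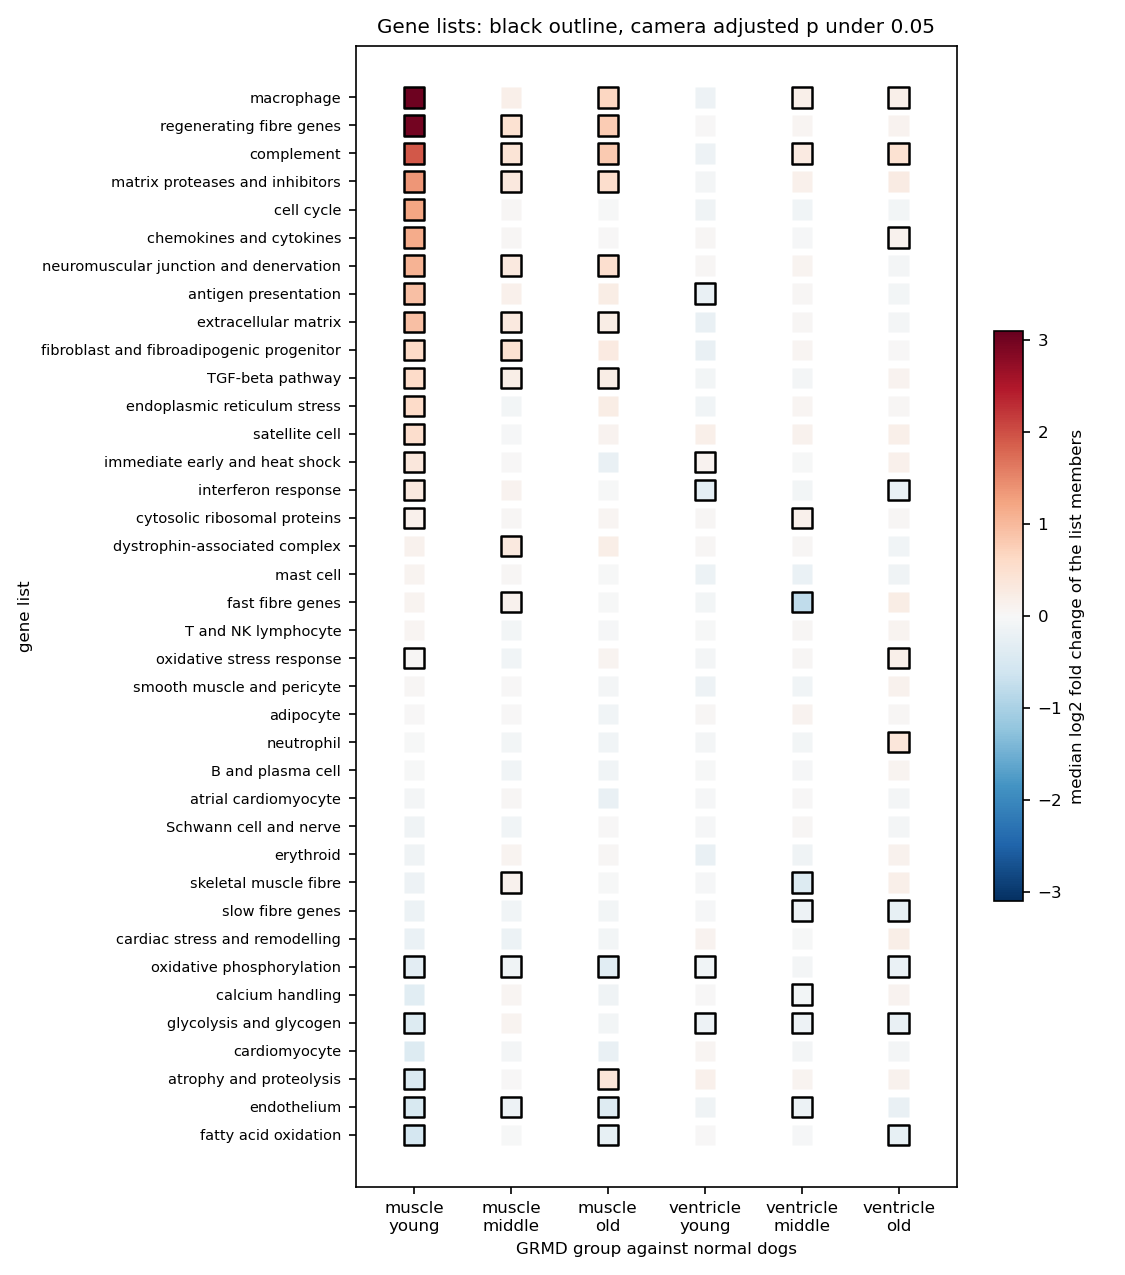
Median log2 fold change of the members of each of 38 gene lists (rows) in 6 comparisons of a GRMD group with normal dogs (columns), red for higher and blue for lower, with a black outline where the camera adjusted p with the preset correlation is under 0.05. Macrophage and regenerating fibre genes are darkest in young muscle (medians 3.03 and 2.99), and 0 of these calls remain with an estimated correlation.

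Within each age class of the ventricle 1 gene passed, DMD, at -1.87 ± 0.21 in young (adjusted p = 0.00142) and -2.21 ± 0.21 in middle dogs (adjusted p = 0.000127, 3 against 3 each). In young dogs ACSL6 (-0.84 ± 0.15, adjusted p = 0.168), PPM1J (-1.26 ± 0.23, adjusted p = 0.168) and PRR32 (2.64 ± 0.50, adjusted p = 0.168) missed. In middle dogs PFKP (1.53 ± 0.26, adjusted p = 0.129), DAO (-1.36 ± 0.26, adjusted p = 0.375) and SERPINB6 (-1.02 ± 0.20, adjusted p = 0.375) did. Young GRMD ventricle was lower as lists for interferon response (camera adjusted p = 0.00172), oxidative phosphorylation (0.00452), glycolysis (0.00956) and antigen presentation (0.0121). In that order these had adjusted p = 0.562, 0.736, 0.562 and 0.562 with an estimated correlation. It was higher for immediate early genes (camera adjusted p = 0.0121, adjusted p = 0.724 with an estimated correlation). Middle GRMD ventricle was higher for complement (camera adjusted p = 0.00130), macrophages (0.00777) and ribosomal proteins (0.00130). These had adjusted p = 0.296, 0.372 and 0.314 with an estimated correlation. It was lower for fast fibre genes (camera adjusted p = 0.000421), skeletal fibre markers (0.00130), slow fibre genes (0.0181), calcium handling (0.00777), glycolysis (0.00130) and endothelium (0.00130), in a comparison that holds the normal array with skeletal fibre transcripts. In that order these had adjusted p = 0.372, 0.372, 0.296, 0.224, 0.296 and 0.372 with an estimated correlation. Unadjusted p under 0.05 were 1072 and 730. By fry 0 lists passed in young and 1 in middle dogs, and with an estimated correlation 0 in each. Without normal young replicate 2 the young count was 2.

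The GRMD effect in the ventricle did not change detectably between the age classes. The change for DMD was -0.34 ± 0.30 (adjusted p = 0.999). Of 15947 genes limma called 0, with 469 at an unadjusted p under 0.05, and with each array left out it was 0 again. The smallest p were those of SCML2 (-1.12 ± 0.26, adjusted p = 0.999), OR51G2 (1.04 ± 0.25, adjusted p = 0.999) and CLEC12A (0.98 ± 0.23, adjusted p = 0.999). Macrophage (camera adjusted p = 0.000391), complement (0.00217), antigen presentation (0.0164) and extracellular matrix genes (0.0485) moved up as lists. In that order these had adjusted p = 0.271, 0.271, 0.554 and 0.928 with an estimated correlation. Fast fibre (camera adjusted p = 0.0114), skeletal fibre (0.0110), calcium handling (0.0110) and cardiomyocyte genes (0.0485) moved down, in a comparison that holds normal middle replicate 3, the ventricle array with skeletal fibre transcripts, and the lists were not tested without it. They had adjusted p = 0.629, 0.629, 0.188 and 0.518 with an estimated correlation. By fry 1 list passed.

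The ventricle of old GRMD dogs differed from that of younger GRMD dogs. DMD did not (0.0014 ± 0.18, adjusted p = 0.999). UCHL1 was higher (4.00 ± 0.28, adjusted p = 9.9e-07), at 9.94 ± 0.54 against 5.20 ± 0.37 in young and 6.67 ± 0.74 in middle GRMD dogs. Normal dogs had 5.30 to 5.87 when young and 7.42 to 7.85 at the middle age, with no old normal group to set age apart. SPP1 rose by 3.00 ± 0.33, with CLGN (2.93 ± 0.39), VAT1L (2.85 ± 0.23) and PCP2 (2.55 ± 0.36). FGFBP1 (-1.86 ± 0.43), FREM2 (-1.55 ± 0.16), the fatty acid desaturase FADS1 (-1.53 ± 0.35), ANGPTL7 (-1.30 ± 0.24) and PCP4L1 (-1.28 ± 0.31) fell. Fatty acid oxidation genes fell in 5 of 25 and in 7 adjusted over the list alone (camera adjusted p = 4.1e-05, adjusted p = 0.187 with an estimated correlation). They include ACSL1 (-1.02 ± 0.17), CPT2 (-0.92 ± 0.20), PPARGC1A (-0.80 ± 0.16) and HADHA (-0.72 ± 0.15). Oxidative phosphorylation was lower with COX15 (-0.72 ± 0.18) (camera adjusted p = 0.0107, adjusted p = 0.685 with an estimated correlation).

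In old GRMD ventricle, complement had CLU (2.00 ± 0.32) and CFI (0.93 ± 0.23) (camera adjusted p = 0.000256, adjusted p = 0.187 with an estimated correlation). Chemokines had SPP1 and CXCL8 (0.98 ± 0.20) (camera adjusted p = 0.000890, adjusted p = 0.187 with an estimated correlation). Macrophages had ADGRE1 (0.71 ± 0.16), 1 of 23 (camera adjusted p = 0.000831, adjusted p = 0.264 with an estimated correlation). Neutrophils had S100A12 (2.25 ± 0.57), with 5 of 11 adjusted over the list alone (camera adjusted p = 0.000256, adjusted p = 0.264 with an estimated correlation). Interferon, antigen presentation, T and NK, B and mast cell lists did not pass. Oxidative stress genes had MT2A (2.30 ± 0.58) and SRXN1 (0.92 ± 0.21) (camera adjusted p = 0.0219, adjusted p = 0.187 with an estimated correlation). Fast fibre genes had MYOZ1 (1.84 ± 0.32) and CASQ1 (1.05 ± 0.22) (camera adjusted p = 0.00954, adjusted p = 0.482 with an estimated correlation). Old replicate 3, from the dog of 93 months, had the highest fast fibre mean of its group (6.65 against 5.40 and 5.26) and the highest S100A12 (10.1 against 7.85 and 6.58). In total 435 genes passed, 157 higher and 278 lower, and 8 of 38 lists, 0 with an estimated correlation and 5 by fry. The count was 183 and 234 without GRMD young replicates 1 and 2, and 225 and 246 without GRMD middle replicates 2 and 3. It was 255 without old replicate 1 and 127 without old replicate 3, where 14 of 24 named genes lost their call.

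Against the younger normal dogs, DMD in old GRMD ventricle was -2.04 ± 0.18 (adjusted p = 1.2e-05). SPP1 (3.67 ± 0.33), CLGN (3.32 ± 0.39), UCHL1 (3.29 ± 0.28), VAT1L (2.94 ± 0.23) and the neurotrophin BDNF (2.66 ± 0.64) were higher. YIPF7 (-2.13 ± 0.41), SMCO1 (-1.96 ± 0.41), TM4SF18 (-1.88 ± 0.46) and GPD1, glycerol-3-phosphate dehydrogenase (-1.65 ± 0.29), were lower beside DMD. Fatty acid oxidation had 4 of 25 lower and 8 adjusted over the list alone (camera adjusted p = 3.6e-06, adjusted p = 0.163 with an estimated correlation), with ACSL1 (-1.12 ± 0.17), CPT2 (-0.89 ± 0.20), HADHA (-0.75 ± 0.15) and ACADVL (-0.73 ± 0.15). Glycolysis had FBP2 (-1.23 ± 0.27), PFKM (-0.89 ± 0.17) and PYGM (-0.58 ± 0.12) lower of 20 (camera adjusted p = 0.000899, adjusted p = 0.163 with an estimated correlation). Slow fibre genes had MYH7B (-1.39 ± 0.16) lower (camera adjusted p = 0.00963, adjusted p = 0.163 with an estimated correlation). Oxidative phosphorylation was lower with 0 of 41 past the threshold (camera adjusted p = 2.5e-06, adjusted p = 0.404 with an estimated correlation). Complement had CLU (1.76 ± 0.32) and CFI (1.28 ± 0.23) and C3 (adjusted p = 0.0124) higher of 15 (camera adjusted p = 3.6e-06, adjusted p = 0.146 with an estimated correlation). Macrophage genes had GPNMB (1.43 ± 0.31) and ADGRE1 (0.71 ± 0.16) higher (camera adjusted p = 0.000545, adjusted p = 0.175 with an estimated correlation). Neutrophil genes had S100A12 (2.52 ± 0.57) (camera adjusted p = 0.00535, adjusted p = 0.399 with an estimated correlation), and chemokine genes SPP1 and CXCL8 (1.08 ± 0.20) (camera adjusted p = 0.00176, adjusted p = 0.163 with an estimated correlation). Oxidative stress genes had MT2A (2.53 ± 0.58) (camera adjusted p = 0.0171, adjusted p = 0.163 with an estimated correlation). The interferon list was lower (camera adjusted p = 0.0496, adjusted p = 0.404 with an estimated correlation) although its 1 member past the threshold, IFI6 (0.52 ± 0.13), was higher.

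In this comparison, where age and disease are mixed, 343 genes passed in the ventricle, 133 higher and 210 lower, and 10 of 38 lists, 0 with an estimated correlation and 10 by fry. The count was 221 without normal middle replicate 2, and 138, 670 and 104 without GRMD old replicates 1, 2 and 3. Without old replicate 3, 17 of 27 named genes lost their call, and without the 3 ventricle arrays that stood apart 56 genes passed. SPP1, CLGN, UCHL1, VAT1L and DMD kept their call with each array left out.

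The GRMD effect was tested for a difference between the tissues of the same dogs, as the ventricle effect minus the muscle effect. The fall of DMD was larger in the ventricle by 0.74 ± 0.20 (adjusted p = 0.0222). MYH3 (-5.03 ± 0.87), MYH8 (-4.30 ± 0.63), ACTC1 (-3.41 ± 0.81), PVALB (-3.34 ± 0.39) and PMAIP1 (-3.31 ± 0.63) had the largest differences of the named genes, each with the stronger rise in muscle. PRR32 (3.25 ± 0.40), FBXO40 (2.25 ± 0.24), METTL21C, a muscle methyltransferase (2.25 ± 0.58), PFKFB1 (2.20 ± 0.39) and ADAMTS8 (2.18 ± 0.37) had the more positive effect in the ventricle. SPP1 (-3.06 ± 0.84) and TIMP1 (-1.56 ± 0.39) rose more in muscle. A set of 4 lists differed with either correlation. These were macrophage (0 higher and 19 lower of 23, 0 and 20 adjusted over the list alone, camera adjusted p = 7.2e-22, adjusted p = 0.0482 with an estimated correlation) and regenerating fibre genes (0 higher and 14 lower of 20, 0 and 16 adjusted over the list alone, camera adjusted p = 2.3e-15, adjusted p = 0.0482 with an estimated correlation). The others were antigen presentation (1 higher and 10 lower of 18, 1 and 12 adjusted over the list alone, camera adjusted p = 2.8e-09, adjusted p = 0.0482 with an estimated correlation) and complement genes (0 higher and 9 lower of 15, 0 and 9 adjusted over the list alone, camera adjusted p = 2.6e-09, adjusted p = 0.0482 with an estimated correlation). Members include GPNMB (-3.30 ± 0.60), AIF1 (-2.76 ± 0.58) and TYROBP (-2.52 ± 0.48) among macrophage genes and CLU (-2.29 ± 0.49), VSIG4 (-2.21 ± 0.42) and C1S (-2.02 ± 0.38) in complement.

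The effect of GRMD was also more negative in the ventricle for extracellular matrix (camera adjusted p = 1.9e-11, adjusted p = 0.107 with an estimated correlation), with FN1 (-2.14 ± 0.49) and COL1A1 (-1.82 ± 0.37). It was for cell cycle (camera adjusted p = 1.5e-10, adjusted p = 0.130 with an estimated correlation), with RRM2 (-1.62 ± 0.34) and MCM6 (-1.42 ± 0.33), and for interferon response (camera adjusted p = 1.9e-05, adjusted p = 0.0790 with an estimated correlation), with OAS2 (-1.38 ± 0.29) and IFIH1 (-0.91 ± 0.20). Fatty acid oxidation (camera adjusted p = 0.00152, adjusted p = 0.408 with an estimated correlation) and oxidative phosphorylation (camera adjusted p = 0.00152, adjusted p = 0.705 with an estimated correlation) were more positive there. In total 1187 genes differed, 362 with a more positive and 825 with a more negative effect in the ventricle, and 17 of 38 lists, 4 with an estimated correlation and 17 by fry. The count was 661 without the dog GRMD young 1, 645 and 722 without normal middle 2 and 3, 726 without GRMD middle 2, and 714 without the 6 arrays that stood apart. Of 62 named genes 18 lost their call without 1 dog or more, 16 of them without GRMD young 1, and DMD lost it without normal young 3, GRMD young 2, normal middle 2 or GRMD middle 2.

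The averaged comparisons of both tissues shared calls on few genes. CCN3 was higher in both (1 gene, 0.336 for independent calls), and ACSL6, ADIPOR2, CMTM8 and DMD were lower in both (4 genes, 0.454 for independent calls). PRR32 was lower in muscle (adjusted p = 0.000200) and higher in the ventricle (2.26 ± 0.35). Genes that rose in muscle and in old against younger GRMD ventricle numbered 36, with 13.2 for independent calls, and genes that fell in both 29, with 15.8. The dogs of both tissues are the same, so the tissues are not independent samples.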

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

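The test of exchanged samples, the contrast of middle against young GRMD muscle and the fits without the arrays that stood apart were chosen after those arrays were seen, and the other tests here were written before their results. The GRMD effect in muscle differed between the age classes by a test of the difference for 362 genes. The largest were MSTN (3.38), FBXO40 (2.73), FRMD3 (2.40), MPP7 (2.27) and FMO2 (2.19), reduced in young dogs and not detectably at the middle age, and GPNMB (-5.50), CCL2 (-5.13), AIF1 (-4.66) and, as bounds, since their young normal levels were dim, SPP1 (-9.81) and MMP12 (-5.48), raised in young dogs and not detectably at the middle age. Part of the change in SPP1 is a higher level in the normal middle dogs (SPP1 3.48 in young and 8.31 in middle normal muscle). The GRMD effect differed between tissues by such a test for 1187 genes, with PRR32 (3.25), FBXO40 (2.25), METTL21C (2.25), PFKFB1 (2.20) and ADAMTS8 (2.18) more positive in the ventricle. MYH3 (-5.03), MYH8 (-4.30), ACTC1 (-3.41), PVALB (-3.34) and PMAIP1 (-3.31) were more negative there. Among 15476 probe sets absent from the annotation table, 575 differed between GRMD and normal muscle and 14 between GRMD and normal ventricle.

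Normal middle muscle replicates 1 and 2 carried regeneration and macrophage transcripts (SPP1 10.93 and 8.66, MYH3 11.05 and 7.67), against 5.32 and 4.06 in replicate 3. An exchange with GRMD muscle is argued against, since the lower DMD of both arrays lay 0.43 above the highest of the 9 GRMD muscle arrays. GRMD muscle RNA in replicate 1, at a share of 37.4%, is left open: 19 genes that differ in both tissues moved 1.37 times as far as predicted (bootstrap interval 0.366 to 2.69), and its DMD, the lowest of the normal muscle arrays at 8.47, lay nearer to the 8.64 predicted than to the normal reference of 9.02, in 1 gene of 1 array. In replicate 2 the implied share is 4.15% and the same genes moved 11.4 times as far as it predicts, so the 1.37 is weak support. Regeneration in these dogs themselves was not tested.

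Fewer genes passed at the middle age in muscle (17) than in young dogs (2859). The normal middle arrays with regeneration transcripts as the whole cause are argued against, since middle and young GRMD muscle, compared without any normal array, differed in 1762 genes. For the change with age (362 genes with all arrays) limma called 0 without both arrays, with 1619 at an unadjusted p under 0.05, and 0 without each of 3 other pairs, so this count decides nothing about them. A part played by these normal arrays stays open. So does age of the dogs, untested apart from these groups.

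Single arrays carried transcripts of the other tissue. In normal young muscle replicate 2, 78.6% of 42 heart genes were highest of the 15 muscle arrays, just under the upper bound set before, so heart RNA (implied share 5.25%) may be the source, and regenerating fibres are argued against by a median of -0.14 in their other genes. In old GRMD ventricle replicate 3, 26.8% of 41 skeletal muscle genes were highest, which is under the bound of 50% set before and by that bound argues against muscle RNA. The bound assumed a single such array, and normal middle ventricle replicate 3 held the highest value for 41.5%, so the question is left open here. Measured after these values were seen, 58.5% and 43.9% of the genes in these ventricle arrays lay above the 13 others (implied shares 1.54% and 1.27%), the latter under the same bound.

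Splits of the same arrays were counted per comparison, the real grouping included, so a count of 1 is that grouping alone. In muscle, 1 of 100 splits gave as many genes as GRMD against normal (2243, highest other 1873). It was 1 of 84 for old GRMD against normal (582, highest other 39), so chance is excluded for both at a share of 0.05. For the change with age (3 of 100, 362, highest other 389) chance stays open: the 389 split keeps young and middle GRMD apart. Old against younger GRMD muscle had 2 of 84 (125, highest other 2241). That split sets young GRMD against the rest, pointing to a structure by age class. In the ventricle, 1 of 100 gave as many as GRMD against normal (12, highest other 1), 1 of 84 as many as old against younger GRMD (435, highest other 16) and 1 of 84 as many as old GRMD against normal (343, highest other 11), and for the tissue difference it was 1 of 100 (1187, highest other 805). For the change with age in the ventricle, where limma called 0 genes (469 at an unadjusted p under 0.05), 100 of 100 splits give as many by construction (highest other 1), which says nothing about chance. With 3 against 3 dogs the 10 splits are too few: young muscle had 2859 (highest other 0), middle muscle 17 (1), middle against young GRMD muscle 1762 (0), young ventricle 1 (0) and middle ventricle 1 (1).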

How the results depend on the processing

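The fits without arrays that stood apart, and the contrast of middle against young GRMD muscle, were chosen after the data were seen. DMD kept its direction in all settings of the comparisons where it passed, and of 11142 values of 608 named gene results under the settings 0 reversed, 9739 stayed on their side of the threshold, 1313 lost the call and 90 gained one. Counts of genes below are those that moved by over 1.5 times, and the cause was not tested unless arrays were left out, which leaves fewer samples. Quantile normalisation within the tissue moved old against younger GRMD muscle from 125 to 68. Testing all probe sets, annotated or not, gave 8 probe sets (6 unannotated) in middle muscle, 133 for the change with age, 20 for old against younger and 257 for old against normal in muscle, and 13, 15, 199 and 227 probe sets (12, 14, 59 and 74 unannotated) for young, middle, old against younger and old against normal ventricle. The variance of each gene alone gave 0, 16, 0 and 186 in the same muscle comparisons, 1073 for middle against young GRMD, and 2, 0 and 193 for GRMD, young GRMD and old GRMD against normal ventricle. Only the compared groups gave 11, 8 and 320 in middle muscle, old against younger and old against normal, and 20, 283 and 144 for GRMD, old against younger and old against normal ventricle. All 30 arrays with the dog as block gave 78, 772, 428 and 999 in the muscle comparisons of middle age, change, old against younger and old against normal, and 24 and 2 for GRMD and young GRMD ventricle. Array weights gave 99, 582 and 239 in middle muscle, change and old against younger, and 58 and 2 for GRMD and middle GRMD ventricle. Leaving out dim probe sets moved no count by over 1.5 times. Without normal middle muscle arrays 1 and 2 the counts were 1303 (GRMD against normal), 29 (middle), 0 by limma for the change (1619 at an unadjusted p under 0.05), 81 and 307 (old), and without normal young array 2 as well 1044, 1819 (young), 26, 0, 29 and 225. Without ventricle normal young array 1, normal middle array 3 and old array 3 (the middle array was added to this fit after its values were seen) they were 1, 144 and 56 for GRMD, old against younger and old against normal, and without these 6 arrays 714 for the tissue difference. A group left with 1 array is assumed to vary like the others. The replicate block gave 5 genes for GRMD against normal ventricle and moved no other count by over 1.5 times. Arrays of the same number did not deviate together, with median correlations of 0.0087 in muscle (-0.094 to 0.266) and -0.021 in the ventricle (-0.099 to 0.189). In middle GRMD, dogs matched by age correlated between tissues at 0.126, 0.145 and 0.156 and those matched by number at 0.126, -0.12 and -0.00067, and the number gave 1175 genes for the tissue difference. No block gave 1063 and the dog as fixed block 1072. With each array left out in turn, counts in muscle ran from 1596 to 2217 (GRMD), 1608 to 2564 (young), 0 to 65 (middle), 87 to 469 (change), 0 to 398 (old against younger), 102 to 1064 (old against normal) and 720 to 1654 (middle against young GRMD). In the ventricle they ran from 1 to 12, 1 to 2, 1 to 1, 0 to 0, 127 to 452 and 104 to 670 in the same order, and for the tissue difference from 645 to 1174. Of the lists that passed with the preset correlation, 0 did with an estimated correlation in any comparison within a tissue and 4 in the tissue difference. By fry the counts of lists that moved were 0 (middle, from 12), 8 (change, from 24), 2 (old against younger, from 13) and 0 (old against normal, from 11) in muscle and 0, 0, 1, 1 and 5 in the ventricle (GRMD, young, middle, change and old against younger, from 10, 5, 9, 8 and 8).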

Other observations

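The contrast of middle against young GRMD muscle was chosen after the data were seen, with normal dogs only in its variance. DMD was higher at the middle age by 0.60 ± 0.18 (3 against 3 dogs, limma adjusted p = 0.0464). SPP1 fell by 4.98 ± 1.05 and TIMP1 by 2.60 ± 0.50, with MMP12 (-4.14), BCL2A1 (-3.74), the macrophage marker MSR1 (-3.62) and CCL2 (-3.58). MSS51 (2.90), FBXO40 (2.77), PFKFB1 (2.59), MYBPC2, a fast fibre myosin binding protein (2.39), and AQP4, the water channel of fast fibres (2.36), rose. Macrophage genes were lower in 19 of 23 and cell cycle genes in 19 of 28, extracellular matrix genes in 15 of 30, and glycolysis genes were higher in 11 of 20. In total 1762 genes passed, 560 higher and 1202 lower, and 23 of 38 lists, 0 with an estimated correlation and 18 by fry. Without GRMD young replicate 1 it was 720, and without GRMD middle replicates 2 and 3 it was 986 and 1071.

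Some arrays stood apart from their group. GRMD young muscle replicate 1 had a macrophage list mean of 8.82, against 7.38 and 7.33. Old GRMD muscle replicate 3, labelled lateral head, had a neutrophil list mean of 5.44, against 4.77 and 4.58. Old GRMD ventricle replicate 3 had S100A8 at 10.59, S100A9 at 9.64 and S100A12 at 10.14. XIST, genes of the Y chromosome, MYH6, NPPA, MYL7, CKM and HBB were not analysed here.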
